A study of Homo sapiens with 44 samples.

How the data were processed

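The deposited values were gene expression intensity per probe set on Affymetrix arrays, which the authors made with the GCOS 1.4 software per the labels. A probe set is a group of short DNA probes that bind 1 transcript, and its intensity rises with the amount of that transcript. The mean after trimming 2% of the probe sets at each end was 500 on every array, which is the mark of a global scaling of each array to 1 target. All values were positive and on a linear scale. The authors' step was not repeated from the scanned images.

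Of 22283 probe sets, 19034 carried 1 gene symbol, 1043 carried several, 2107 carried none and 68 were control probe sets. XIST and Y-linked genes (31 probe sets) were left out of every table. A gene was represented by the probe set with the highest mean over the 44 arrays among those of 1 symbol, which gave 11939 genes. Array medians ranged from 136 to 237, a 1.74-fold span. That span exceeded the limit of 1.5 fixed before the data were examined, so intensities were quantile normalized, a step that gives every array the same distribution of values. A pseudocount of 17.2, the 10th percentile of all values, was then added and log2 taken. Values as deposited and values centred on each array's median served as alternatives.

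Groups were compared with limma 3.58.1 in R 4.3.3, which fits a linear model per gene and steadies each gene's variance with that of all genes. Adjusted p values of single genes are limma's moderated test after Benjamini-Hochberg correction over all genes tested in that comparison, two-sided. A gene is called when its adjusted p is under 0.05. A gene was tested when its signal exceeded the array's median on at least 3 arrays of the fit. Differences are log2 values with a standard error (SE). The 30 patients are separate persons and enter as 30 independent values. Each normal group holds the same 3 subjects, so the normal groups were also compared with the subject as a block. The 18 correlations between a subject's deviations in any pair of normal groups ranged from 0.0478 to 0.584 with a median of 0.0995. The choice of groups, comparisons, gene lists, threshold and alternatives was made before the data were examined, with the exceptions named as chosen later.

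The numbers in the sample titles form 1 running series that holds 27 patients and both pooled normal samples. The other 3 patients and all 12 arrays of the normal subjects lie outside it. The labels do not say what the series is, and it was treated as a possible batch. No normal subject's array lies inside the series and only 2 pooled arrays are controls within it. Each comparison with patients was therefore also fitted with the number series as a term and with only the 3 outside patients. The fit with the term held all 44 arrays, with each pooled sample counted in its resting normal group. The comparisons with resting PBMC and resting CD8-enriched cells were also fitted with the 27 inside patients against the pooled sample. Against normal PBMC a fit took the log2 GAPDH 3' to 5' ratio of each array as a term. These fits were chosen after the data were seen. So were the fits without 1 normal subject that test the same genes as with all, added because the filter drops genes that only 1 group of 3 arrays expresses.

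Gene lists numbered 22 and held 436 different genes. They were cytotoxic granule (16 genes, 14 on the array), natural killer (NK) receptor (24, 18), naive and central memory T cell (19, 17), CD4 and regulatory T cell (14, 13), pan T cell receptor (17, 16), B cell (18, 16), monocyte (20, 19), dendritic cell (10, 9), neutrophil (16, 15), platelet (15, 13), red cell (15, 8), cell cycle (26, 26), immediate early and stress (26, 23), interferon stimulated (21, 20), sphingolipid (42, 35), apoptosis and survival (25, 21), cytokine receptor and JAK-STAT (25, 25), chemokine and cytokine of cytotoxic cells (20, 17), T cell activation marker (20, 18), glycolysis (15, 15), cholesterol synthesis (17, 12) and ribosomal protein (24, 17). Of the 436 genes, 8 are in more than 1 list: CTLA4, CX3CR1, GZMB, ICOS, IL2RA, LTA, S1PR5 and TNFRSF4. Each list was tested with camera from limma at its preset correlation of 0.01, which compares the list's genes with all other genes. Camera with a correlation estimated from the data and fry, which asks whether the list's genes move one way, were run beside it. Camera and fry p values were adjusted over the lists tested in a comparison. A list with under 3 tested genes was not tested, which left the red cell list out where no patients were compared: only HBB and CA1 were measured there.

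Genes named in the text follow a rule. They are the 6 largest rises and 6 largest falls among called genes whose group medians moved the same way, and up to 4 called members per list with the smallest adjusted p. GZMB, PRF1, GNLY, CX3CR1, CCR7, IL7R, S1PR5, S1PR1, ASAH1, SGPP1, FAS, FASLG and MCL1 are named in every comparison. For genes that set patients apart from all 4 normal groups, the 10 with the largest smallest difference are named. Immunoglobulin and T cell receptor segments, HLA and KIR genes, and GSTM and globin copies outside a list are not named singly. Genes named only for a value with the series term were chosen after their values were seen.

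A simulation put known changes into 100 genes on arrays drawn with each gene's observed spread. For patients against PBMC the test recovered 38% of changes of 2-fold and 90% of changes of 4-fold. For activation in PBMC it recovered 34% and 69%, for enrichment after activation 20% and 68%, and for the difference between both activations 1% and 38%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, permutation tests and plots.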

Results

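Gene expression was measured on 44 Affymetrix arrays with RNA from human peripheral blood mononuclear cells (PBMC, the lymphocytes and monocytes of blood). T-LGL leukaemia is a chronic expansion of large granular lymphocytes, which are cytotoxic T cells loaded with killing enzymes. PBMC of 30 patients with this leukaemia were hybridised, 1 array each. Each of 3 normal subjects gave 4 arrays. These were resting PBMC, resting PBMC enriched for CD8 cells, PBMC activated for 10 days, and activated PBMC then enriched for CD8 cells. Activation used phytohaemagglutinin, a plant lectin that drives T cells to divide, together with interleukin 2. A pooled normal PBMC sample and a pooled normal CD8-enriched sample made up the rest. The comparisons set leukaemic blood beside normal resting cells and beside normal cells in full activation, with the sphingolipid pathway and cell survival in view.

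The median deposited intensity of an array lay between 139 and 237 among patients and between 189 and 200 in normal PBMC. It lay between 161 and 171 in CD8-enriched cells, between 147 and 169 in activated PBMC and between 136 and 189 in activated CD8-enriched cells. The pooled samples had medians of 171 and 178. The number of arrays, 3 in each normal group, limits the precision of every comparison. Correlations between arrays of the same group ranged from 0.798 to 0.962 among patients and from 0.908 to 0.937 among normal subjects. In 2 patient arrays the signal of the 3' end of ACTB or GAPDH exceeded that of the 5' end by more than 3-fold, a mark of RNA breakdown. Without them 949 genes were called against normal PBMC, beside 932 with them. With the log2 GAPDH ratio of each array as a term 837 were called. Without those 2 arrays it was 282. The mean log2 ratio of the 3' to the 5' end in patients was 0.63 ± 0.74 for ACTB and 0.21 ± 0.88 for GAPDH (SD, n = 30). By exact permutation tests, two-sided and adjusted over 8 tests, the ACTB ratio was higher in patients than in activated PBMC by 0.82 (p = 0.0044) and than in activated CD8-enriched cells by 0.64 (p = 0.00587). The GAPDH ratio was higher than in normal PBMC by 0.63 (p = 0.0044) and than in CD8-enriched cells by 0.48 (p = 0.0337), while the other 4 differences had adjusted p of 0.197 to 0.997.

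**Figure D1:**
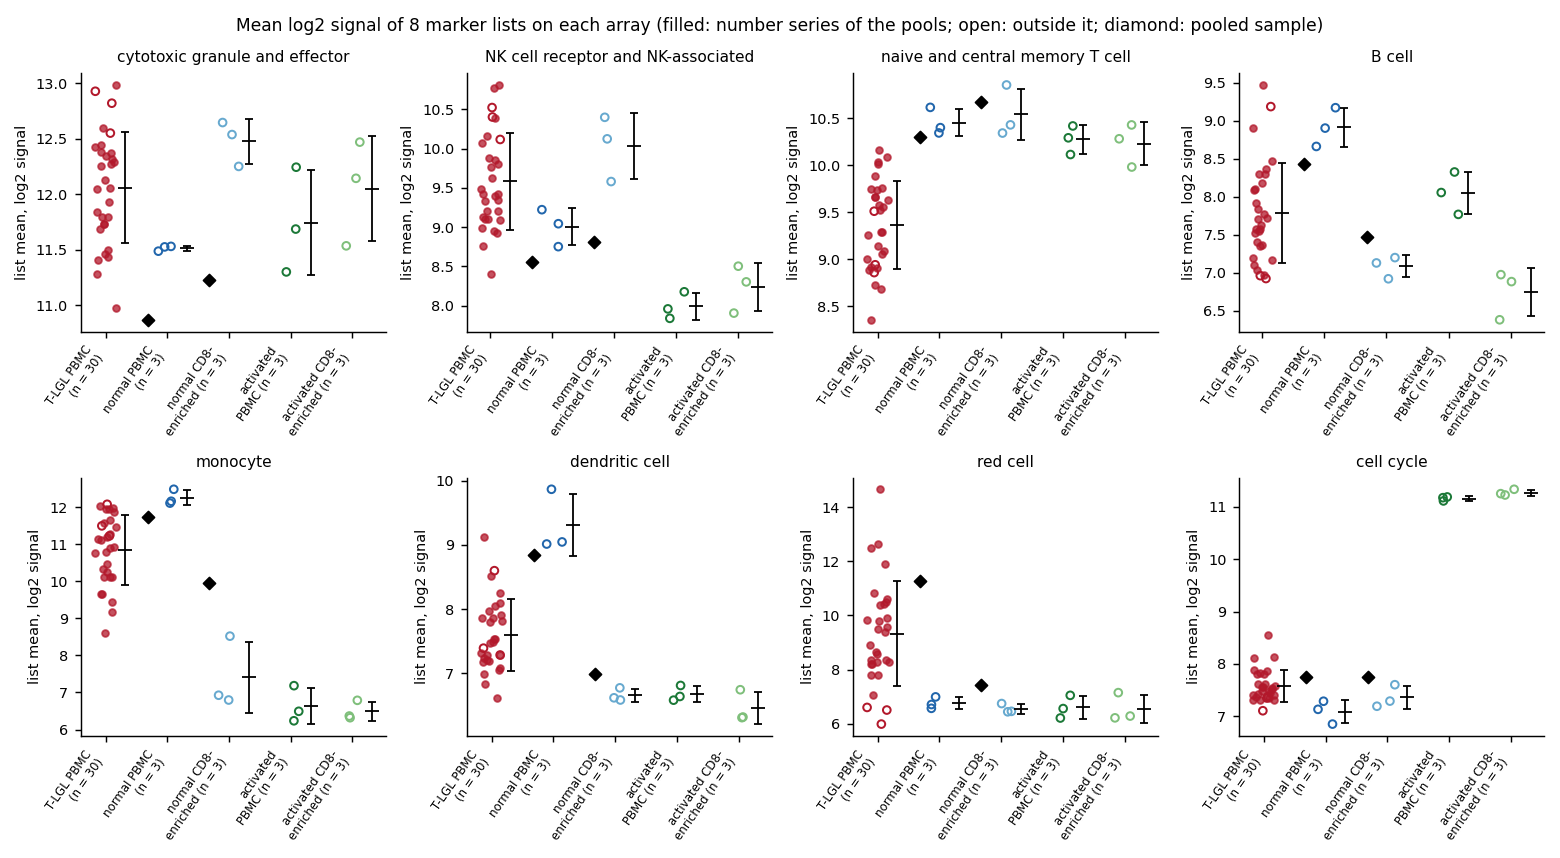
Mean log2 signal of 8 gene lists on each array (y axis) by group (x axis); points are arrays, filled inside the number series of the pooled samples and open outside it, diamonds are pooled samples, and bars give the mean and SD of 30 patients or 3 subjects. Against normal PBMC the naive T cell list had a median difference of -0.85 in patients and the monocyte list -1.35, and patients outside the number series lay with the normal arrays on the red cell list.

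The first comparison asked how blood of T-LGL patients differs from normal resting PBMC. Values on patients are log2 differences ± SE, n = 30 and 3, here and in all that follows, except in fits that add or leave out arrays. Several effector genes were higher in patient cells, though the cytotoxic list as a whole was not called. GZMH (a granzyme, a protease of cytotoxic granules) was higher by 2.06 ± 0.56, NKG7 (a granule membrane protein) by 1.68 ± 0.33 and SERPINB9 (the inhibitor that shields a killer cell from its own granzyme B) by 2.04 ± 0.34. The transcription factors of effector T cells TBX21 (2.10 ± 0.40) and ZEB2 (2.74 ± 0.42, adjusted p = 5.2e-05) were higher as well. So were the NK receptor NCR1 (1.70 ± 0.29), the adhesion receptor ADGRG1 of terminal effector cells (2.54 ± 0.54) and the motor protein MYO6 (3.30 ± 0.55, adjusted p = 0.000182). The chemokines CCL5 (2.12 ± 0.39) and CCL4 (2.54 ± 0.58) and the cytokine IFNG (2.58 ± 0.73) were higher.

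Of the naive T cell list 5 of 17 genes were lower in patients. The list did not pass with an estimated correlation (adjusted p = 0.122). The co-stimulatory receptors CD27 and CD28, lost as T cells age into effectors, differed by -2.21 ± 0.47 and -1.53 ± 0.36. The kinase TXK (-1.69 ± 0.42) and the naive cell marker FHIT (-1.41 ± 0.34) were lower too. CD4, the helper co-receptor (-1.31 ± 0.39), and the homing receptor CCR6 (-1.26 ± 0.41) were lower, while the CD4 T cell list was not called. GZMK, the granzyme of early memory cells, was lower (-2.29 ± 0.62), the opposite of GZMH. Of the B cell genes 5 of 14 were lower, among them VPREB3 (-1.99 ± 0.44), CD79B (-1.86 ± 0.53) and BANK1 (-1.81 ± 0.56), all parts of B cell receptor assembly or signalling. None was called with the number series as a term. Of the dendritic cell genes 3 of 8 were lower, the IgE receptor chain FCER1A at -3.57 ± 0.61, the lipid presenter CD1C at -2.92 ± 0.82 and the lectin CLEC10A at -2.02 ± 0.53. Monocyte genes LGALS2 (-3.52 ± 1.12), CYP27A1 (-3.03 ± 0.87), RNASE6 (-3.03 ± 0.97), CD36 (-2.21 ± 0.64) and MS4A6A (-1.99 ± 0.65), the platelet tubulin TUBB1 (-2.48 ± 0.71) and the clotting factor F13A1 (-1.80 ± 0.57) were lower. The cytokine OSM had the smallest adjusted p of all named genes here (-3.68 ± 0.41, p = 5.1e-07).

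In the sphingolipid pathway, which balances ceramide that promotes death against sphingosine 1-phosphate that promotes survival, 4 genes were higher and 2 lower of 29 tested. The phosphatases SGPP1 (1.05 ± 0.23) and PLPP1 (1.71 ± 0.40), which remove phosphate from sphingosine 1-phosphate and other lipids, were higher, and so was the lysosomal sulfatase ARSA (2.16 ± 0.37). CERS6, a ceramide synthase, was lower (-1.60 ± 0.34). ASAH1, which breaks ceramide down, differed by -0.09 ± 0.27 and was not called. The receptors of sphingosine 1-phosphate were not called either, with S1PR5 at 1.96 ± 0.88 and S1PR1 at -0.30 ± 0.46. Of survival and cytokine signalling genes, STAT3 (0.95 ± 0.29), IL21R (1.29 ± 0.33), the inhibitory receptor LAG3 (2.32 ± 0.58), the co-stimulatory receptor TNFRSF9 (1.57 ± 0.42) and the tryptophan enzyme IDO1 (2.59 ± 0.77) were higher. SOCS2, a brake on cytokine signals, was lower (-1.73 ± 0.39), as was the interleukin 18 receptor chain IL18RAP (-1.78 ± 0.53). The regulators PPP1R10 (2.81 ± 0.48) of nuclear phosphatase and IKZF2 (1.77 ± 0.55) of T cell identity were higher, as were the interferon response gene IFIT2 (1.33 ± 0.43), the glucose carrier SLC2A1 (0.74 ± 0.24) and the sterol enzyme LSS (0.85 ± 0.25). GZMB (1.16 ± 0.44, adjusted p = 0.081), PRF1 (1.42 ± 0.48, adjusted p = 0.051), CD8A (1.67 ± 0.70), CD8B (1.51 ± 0.53), GNLY (-0.29 ± 0.87), CX3CR1 (1.33 ± 1.05), CCR7 (-0.71 ± 0.63), IL7R (-1.86 ± 0.63), FAS (0.45 ± 0.41), FASLG (0.94 ± 0.40), MCL1 (-0.39 ± 0.21) and BCL2 (-1.40 ± 0.48) were not called. The haemoglobin chains HBB (5.22 ± 1.26) and HBD (3.82 ± 1.28) were called higher, yet HBB reversed to -0.19 ± 0.71 and HBD to -0.35 with the number series as a term. Calls of HBD, ANKRD55, TCL1A, MAD2L1, TPX2, BCL2L1 and MSMO1 did not pass under every scaling.

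In limma 932 genes were called against normal PBMC, 694 higher and 238 lower of 8696 tested. The B cell list fell (5 of 14 genes lower, 9 lower and 1 higher adjusted over the list alone, median -1.42, camera adjusted p = 2.5e-05, adjusted p = 0.462 with an estimated correlation). The monocyte list fell (2 of 19 lower, 3 adjusted over the list alone, median -1.35, adjusted p = 2.8e-06, and 0.462 with an estimated correlation). The naive T cell list fell (5 of 17 lower, 8 adjusted over the list alone, median -0.85, adjusted p = 1.7e-07, and 0.122 with an estimated correlation). The dendritic cell list fell (3 of 8 lower, 4 adjusted over the list alone, median -1.66, adjusted p = 2.5e-05, and 0.0657 with an estimated correlation). The platelet list fell (median -1.25, adjusted p = 0.00346, and 0.546 with an estimated correlation) and the ribosomal list shifted down by a median of 0.16 (adjusted p = 0.0145, and 0.546 with an estimated correlation). The cell cycle list rose (2 of 20 higher, 4 adjusted over the list alone, median 0.56, adjusted p = 0.0209, and 0.546 with an estimated correlation), as did the red cell list (2 of 8, median 2.08, adjusted p = 0.0252, and 0.717 with an estimated correlation). The cytotoxic list (4 higher and 1 lower of 14, 7 higher and 2 lower adjusted over the list alone, median 0.85) and the NK list (3 of 18 higher, median 0.40) had camera adjusted p of 0.128 and 0.38.

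The other 12 lists were not called against normal PBMC by camera, and their adjusted p ran from 0.073 to 0.892. Median differences were -0.08 for the CD4 T cell list, 0.17 for pan T cell, -0.13 for neutrophil, -0.22 for immediate early, 0.13 for interferon, 0.14 for sphingolipid and 0.10 for apoptosis. They were 0.16 for cytokine receptor, 0.27 for chemokine, 0.00 for T cell activation, -0.06 for glycolysis and 0.07 for cholesterol. Adjusted over the list alone, 6 sphingolipid genes were higher and 3 lower.

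Without the first, the second or the third normal PBMC array the count against normal PBMC was 481, 308 and 409, and 30, 41 and 33 of the 57 named genes lost their call. MYO6, PPP1R10, ZEB2, OSM, FCER1A, SERPINB9, NKG7, NCR1, TBX21, ADGRG1, CD27, ARSA, CERS6 and CCL5 kept it each time, and VPREB3 did where it stayed among the genes tested. With the number series as a term 160 genes were called, 91 of them shared in direction, and with only the 3 outside patients 254. Of the 57 named genes, 18 kept their call with the term, among them MYO6 (2.75 ± 0.55), ZEB2 (1.71 ± 0.39), GZMH (2.93 ± 0.56), NKG7 (1.99 ± 0.33), ADGRG1 (2.88 ± 0.55), IFNG (2.94 ± 0.68), PLPP1 (1.61), TBX21 (1.42), CD28 (-1.49), FHIT (-1.77), CD4 (-1.64), FCER1A (-2.69 ± 0.61) and OSM (-2.18 ± 0.46). Calls of PPP1R10 (1.14), CD27 (-1.23), ARSA (0.61), CERS6 (-0.80), SGPP1 (0.77), GZMK (-0.95) and VPREB3 (-1.28) were lost with it. CX3CR1, the chemokine receptor of terminal killers, was called with the term, near the threshold (3.52 ± 0.98, adjusted p = 0.0494). That fit counts the pooled PBMC array, where CX3CR1 had a log2 signal of 7.09, beside 9.31, 10.56 and 11.78 on the subjects' PBMC arrays. S1PR5 (3.39 ± 0.76), the protease PRSS23 (3.11 ± 0.64) and TOX (2.82 ± 0.50), a regulator of persistent T cell stimulation, were called with the term too.

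With the number series taken into account, the medians of the cytotoxic, NK, naive T, B, monocyte, dendritic and platelet lists against normal PBMC kept their sign. That of the red cell list reversed, and that of the cell cycle list came near 0. The cytotoxic list, not called without the term, had a median of 1.31 with it (6 of 14 genes higher, camera adjusted p = 4.0e-09, and 0.0164 with an estimated correlation), 1.38 in the 3 outside patients and 1.18 in the 27 inside patients against the pooled sample. The NK list, also not called without the term, had 1.22 (6 of 18 higher, adjusted p = 5.2e-06, and 0.0678 with an estimated correlation), 1.39 and 0.80 in the same fits. The naive T cell list had -1.28, -1.60 and -0.97, the B cell list -1.04, -1.35 and -0.75, the monocyte list -1.22, -0.71 and -1.11, and the dendritic list -1.36, -1.52 and -1.27. With the term and an estimated correlation the naive T cell and dendritic lists had adjusted p = 0.0164, the B cell list 0.192 and the monocyte list 0.284, and limma called 0 single genes of the last pair, which had been 5 and 2 without the term. The platelet list had -1.36, -1.23 and -2.18. The red cell list had -0.52, -0.71 and -1.51, and the cell cycle list 0.03, 0.10 and -0.10. The sphingolipid list had 0.02, -0.04 and 0.06. The fit of the 27 patients has a single pooled array as its control, so only medians are given for it. The series term itself was called for 2644 of 9097 genes.

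**Figure D2:**
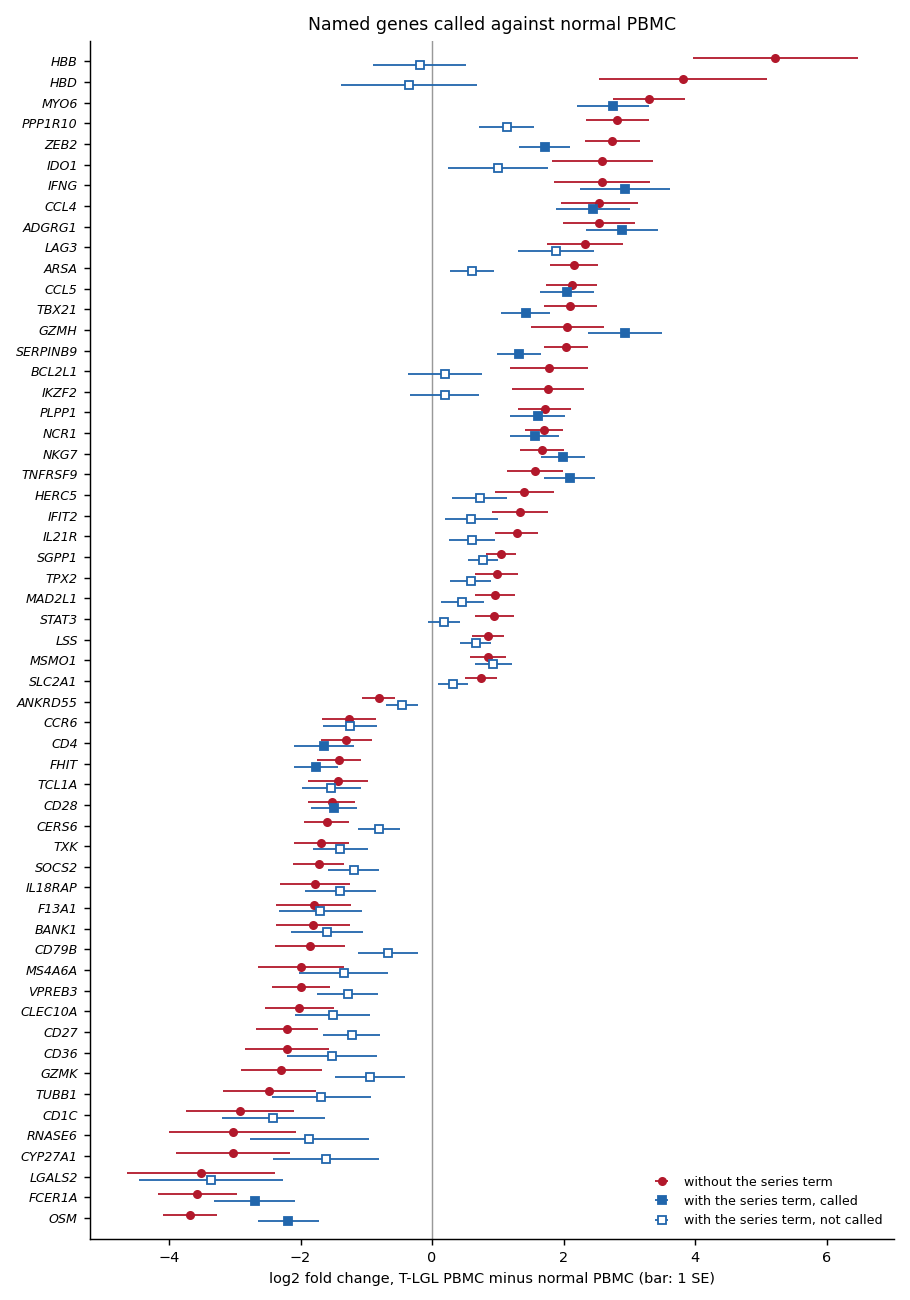
Log2 difference between T-LGL PBMC and normal PBMC (x axis) for named genes called in that comparison (y axis). Circles are values without the number series as a term (n = 30 and 3). Squares are values with it, from the fit on all 44 arrays with the pooled samples in the normal groups, filled where called. Bars are 1 SE. ZEB2 stayed higher (2.74 without and 1.71 with the term) and OSM lower (-3.68 and -2.18), while HBB moved from 5.22 to -0.19.

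Against normal CD8-enriched cells, the nearest normal counterpart of the leukaemic cell, patient PBMC were still lower in 8 of 17 naive T cell genes. GZMK differed by -4.23 ± 0.62 (adjusted p = 2.1e-05), the enzyme AKR1C3 by -4.16 ± 0.66, CD27 by -2.57 ± 0.47, CD28 by -1.80 ± 0.35, NELL2 (a secreted protein of naive CD8 cells) by -2.18 ± 0.45 and TXK by -2.32 ± 0.42. The cytokine receptor chains IL18RAP (-3.01 ± 0.53) and IL12RB2 (-2.59 ± 0.43) and the chemokine receptor CXCR3 (-2.40 ± 0.63) were lower. The survival cytokine receptor IL7R (-2.27 ± 0.62), the death inhibitor BCL2 (-1.45 ± 0.48) and its antagonist BAX (-1.98 ± 0.57) were lower. The signalling genes SKIL (-3.27 ± 0.72), DUSP4 (-3.17 ± 0.78) and JUN (-2.23 ± 0.56), the chromatin protein HP1BP3 (-3.26 ± 0.70) and the NK receptors NCAM1 (-2.33 ± 0.59) and NCR3 (-2.05 ± 0.53) were lower as well.

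SERPINB9 (1.42 ± 0.34), TBX21 (1.43 ± 0.40) and STAT3 (1.34 ± 0.29) were higher in patients than in CD8-enriched cells. Monocyte genes led the other rises. These were LYZ (lysozyme, 6.38 ± 0.59, adjusted p = 3.7e-09), MARCKS (6.04 ± 0.61), CD14 (5.46 ± 0.92), FCN1 (5.40 ± 0.82), VCAN (5.31 ± 0.66), SERPINA1 (5.26 ± 0.73), the co-stimulatory CD86 (4.25 ± 0.44), CCR1 (3.12 ± 0.52) and CD4 (3.09 ± 0.41). The antigen presentation chain CD74 (2.21 ± 0.35), the regulator IRF4 (1.46 ± 0.41) and the chemokines CXCL8 (4.01 ± 0.96) and CXCL2 (3.87 ± 0.91) were higher too. Of the sphingolipid list, which was not called as a whole, GM2A (2.90 ± 0.50), PSAP (2.25 ± 0.43), the kinase SPHK1, which makes sphingosine 1-phosphate (2.08 ± 0.49), and ASAH1 (1.33 ± 0.28) were higher. Patient PBMC were not enriched, and CD8 enrichment of resting normal PBMC itself lowered monocyte genes, GM2A, PSAP and ASAH1. Against whole normal PBMC ASAH1 was not called. The rises of monocyte and sphingolipid genes therefore cannot be assigned to the leukaemic cells. Falls carry a like limit, since enrichment of resting normal PBMC itself raised GZMK and, by camera at its preset correlation, the pan T cell list. Against whole normal PBMC GZMK differed by -2.29, and CD27, CD28, TXK and IL18RAP were lower there too. The B cell genes PAX5 (1.88 ± 0.50), SPIB (1.41 ± 0.43) and BLK (0.78 ± 0.24), HBB (4.90 ± 1.26), the mitotic kinase CDK1 (1.14 ± 0.27), the sugar kinase HK2 (2.45 ± 0.77) and the sterol enzyme SQLE (1.67 ± 0.34) were higher. PRF1 (0.70 ± 0.48), GZMB (-0.27 ± 0.43), GNLY (-1.37 ± 0.87), CX3CR1 (1.16 ± 1.05), S1PR5 (-1.13 ± 0.89), S1PR1 (-0.25), SGPP1 (0.52 ± 0.23), FAS (0.72), FASLG (-0.31), MCL1 (0.28) and CCR7 (-0.95 ± 0.63) were not called.

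Limma called 1524 genes against CD8-enriched cells, 1054 higher and 470 lower of 8699, so 69.2% were higher, a share of 57.8% under median centring. With the number series as a term 202 were called higher and 181 lower. Of the 59 named genes called, 55 kept their call under both other scalings. The monocyte list rose (16 of 19 genes, 18 adjusted over the list alone, median 3.17, camera adjusted p = 2.8e-13, adjusted p = 0.166 with an estimated correlation) and the naive T cell list fell (8 of 17, 9 adjusted over the list alone, median -1.13, adjusted p = 3.1e-07, and 0.166 with an estimated correlation). The pan T cell list fell (no member called, median -0.48, adjusted p = 0.0382, and 0.474 with an estimated correlation), the ribosomal list fell (3 of 17, median -0.30, adjusted p = 0.00216, and 0.474 with an estimated correlation) and the red cell list rose (2 of 8, 4 adjusted over the list alone, median 2.90, adjusted p = 0.0389, and 0.742 with an estimated correlation). The cytotoxic and NK lists had medians of -0.19 and -0.66 and adjusted p of 0.252 and 0.155. Of the sphingolipid list 7 of 29 genes were higher and 1 lower (9 and 2 adjusted over the list alone, median 0.34, adjusted p = 0.109). The T cell activation list had 5 of 16 genes higher (median 0.69, adjusted p = 0.105), and the other 13 lists had adjusted p of 0.109 to 0.913.

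Without each CD8-enriched array in turn, 726, 574 and 836 genes were called and 22, 27 and 21 of the 59 named genes lost their call. LYZ, GZMK, AKR1C3, IL18RAP, TXK, CD27, CD28, NELL2, GM2A, PSAP, ASAH1 and STAT3 were among the 24 that kept it each time. With the number series as a term 383 genes were called, 253 of them shared in direction, and with only the 3 outside patients 466. Of the 59 named genes 25 kept their call with the term, among them GZMK at -2.71, CD27 at -1.58, CD28 at -1.73, NELL2 at -2.69, AKR1C3 at -3.29, ASAH1 at 1.04 and LYZ at 4.19. The other 34 did not, among them HP1BP3 (-0.21), IL12RB2 (-0.54), NCAM1 (-1.79), NCR3 (-1.43), BCL2 (-0.34), BAX (-0.42), SERPINB9 (0.82), TBX21 (0.78), STAT3 (0.40), SPHK1 (0.91), CXCL8 (2.16), HK2 (0.89) and HBB (-0.06). The naive T cell list then had a median of -1.48 (8 of 17 lower, adjusted p = 1.8e-12, and 0.0166 with an estimated correlation), the monocyte list 2.49, the T cell activation list 0.93 (6 of 16 higher, adjusted p = 3.0e-05, and 0.0166 with an estimated correlation) and the red cell list 0.61. The cytotoxic list turned from -0.19 to 0.71 with the term (adjusted p = 0.0235, and 0.534 with an estimated correlation), to 0.37 in the 3 outside patients and to 0.76 for the 27 inside patients against the pooled CD8-enriched sample, so its direction was not settled. The NK list turned to 0.52, 0.73 and 0.82 in the same fits, the naive T cell list had -1.57 and -1.33 in the last pair, and the monocyte list 3.78 and 0.78. The pooled CD8-enriched sample is a single array, so only medians are given for that fit. Its monocyte list mean was 9.9611, beside 6.7973, 6.9264 and 8.5202 on the subjects' CD8-enriched arrays. Its cytotoxic list mean was 11.2275, beside 12.252, 12.6475 and 12.5391. The pool also enters the fit with the series term, so neither fit parts its cell content from the series. The fit of the 3 outside patients does not use the pool.

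Against activated PBMC the replication programme was lower in patient cells. RRM2, which makes DNA building blocks, differed by -6.04 ± 0.36 (adjusted p = 2.5e-15), CDC45 (a part of the replication helicase) by -5.23 ± 0.21, TOP2A (topoisomerase) by -5.50 ± 0.55, ASPM (a spindle protein) by -5.70 ± 0.48, CDK1 by -4.18 ± 0.24 and MKI67 (a marker of dividing cells) by -3.17 ± 0.20. The T cell activation list had 8 of 17 genes lower and 1 higher and did not pass with an estimated correlation (adjusted p = 0.211). Lower single genes were the interleukin 2 receptor IL2RA at -4.48 ± 0.39 (adjusted p = 3.7e-11), ICOS at -3.19 ± 0.69, CTLA4 at -2.26 ± 0.63, LTA at -3.83 ± 0.37, LIF at -5.09 ± 0.34, CD70 at -2.68 ± 0.29, IL12RB2 at -3.96 ± 0.44 and the feedback inhibitor SOCS1 at -2.76 ± 0.41. Glycolysis enzymes ENO1 (-2.49 ± 0.35), GPI (-2.48 ± 0.39), GAPDH (-1.20 ± 0.21) and LDHA (-1.47 ± 0.33) were lower, and so were BCL2 (-2.35 ± 0.49) and BAX (-2.53 ± 0.57).

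Some effector genes exceeded the activated level, while the cytotoxic list as a whole was not called. ADGRG1 was higher by 5.12 ± 0.55 (adjusted p = 5.5e-09), CX3CR1 by 4.16 ± 1.04, the receptor adaptor TYROBP by 3.59 ± 0.61, GZMH by 2.92 ± 0.58, TBX21 by 2.02 ± 0.41, SERPINB9 by 1.92 ± 0.33, NKG7 by 1.88 ± 0.35 and PRF1, the pore-forming perforin, by 1.65 ± 0.48. The death inhibitor MCL1 was higher by 1.29 ± 0.20 and the death protease CASP8 by 1.61 ± 0.35. In the sphingolipid pathway PSAP (3.47 ± 0.44), ASAH1 (2.25 ± 0.28, adjusted p = 7.4e-08) and SGPL1, which degrades sphingosine 1-phosphate (1.28 ± 0.21), were higher and PLPP1 was lower (-1.97 ± 0.35). PSAP, ASAH1, MCL1, CX3CR1 and monocyte genes fell on activation of normal PBMC, so here they were measured against a lowered reference. The same applies to ADGRG1, with log2 signals of 8.94 to 9.83 on the resting and 5.75 to 7.41 on the activated PBMC arrays. Against resting PBMC ASAH1, MCL1 and CX3CR1 were not called. The alarmins S100A8 (7.94 ± 0.54) and S100A9 (5.97 ± 0.84), CD14 (6.12 ± 0.90), the platelet chemokine PPBP (5.84 ± 0.88), HBB (6.55 ± 1.27) and the early response genes DUSP1 (4.65 ± 0.71), ZFP36 (3.25 ± 0.41) and TNFAIP3 (2.54 ± 0.42) were higher. GZMB (-0.30 ± 0.43), GNLY (-0.38 ± 0.88), FAS (-0.89 ± 0.41), FASLG (-0.24 ± 0.40), SGPP1 (0.28) and S1PR1 (0.50 ± 0.46) were not called. Nor were CCR7 and IL7R. The call of S1PR5 (2.19 ± 0.88) did not pass under every scaling, as was so for CCR4, IFIT3, RPL30 and RPS25.

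Limma called 3284 genes against activated PBMC, 1803 higher and 1481 lower of 8780, a share higher of 54.9% and of 44.8% under median centring. The cell cycle list fell in all 26 genes (also 26 adjusted over the list alone, median -3.56, camera adjusted p = 2.7e-34, and 5.7e-05 with an estimated correlation). Glycolysis fell (11 of 15, median -1.09, adjusted p = 5.2e-05, and 0.336 with an estimated correlation), the T cell activation list fell (8 of 17 lower and 1 higher, median -0.62, adjusted p = 0.00379, and 0.211 with an estimated correlation) and the naive T cell list fell (7 lower and 1 higher of 17, median -0.80, adjusted p = 0.0156, and 0.451 with an estimated correlation). The monocyte list rose (18 of 19, median 4.10, adjusted p = 1.3e-11, and 0.192 with an estimated correlation), as did the immediate early list (12 of 23, 13 adjusted over the list alone, median 1.31, adjusted p = 0.000163, and 0.451 with an estimated correlation) and the NK list (9 higher and 2 lower of 18, median 1.43, adjusted p = 0.0156, and 0.451 with an estimated correlation). The neutrophil list (median 1.80, adjusted p = 0.0454) and the platelet list (median 0.86, adjusted p = 0.0188) rose too, with p of 0.56 and 0.501 with an estimated correlation. The sphingolipid list had 11 genes higher and 4 lower of 29 (median 0.50, adjusted p = 0.132), the cytotoxic list 5 higher and 3 lower of 14 (median 0.18, adjusted p = 0.526), and the other 11 lists adjusted p of 0.0646 to 0.978.

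Counts against activated PBMC were 2094 to 2365 without 1 of the activated arrays, the lowest without the first. Of the 85 named genes, 16, 14 and 8 lost their call without the first, the second or the third, with the same genes tested. With the number series as a term 1764 genes were called, 1401 of them shared in direction, and 2057 with only the 3 outside patients. The cell cycle list then had medians of -3.94 and -3.91, the NK list 2.21 and 2.89, the cytotoxic list 0.85 and 0.94, the monocyte list 4.03 and 4.91, glycolysis -1.35 and -1.26 and the red cell list -0.07 and 0.77. With the term CX3CR1 was higher by 5.98 ± 1.18 and S1PR5 by 4.17 ± 0.91. Of the 85 named genes 64 kept their call with it, and HBB (1.17) was among those that did not.

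Activated CD8-enriched cells are the normal match for an activated cytotoxic T cell. Beside them patients were again lower in division genes, with RRM2 at -5.85 ± 0.36 (adjusted p = 4.5e-15), CDC45 at -5.23 ± 0.22, TYMS (thymidylate synthesis) at -5.25 ± 0.38, CDK1 at -4.29 ± 0.25 and MKI67 at -3.48 ± 0.20. IL2RA (-4.25 ± 0.39), ICOS (-2.95 ± 0.69), LTA (-3.09 ± 0.38), IL12RB2 (-4.04 ± 0.44), the cytokine brake CISH (-3.01 ± 0.44), ENO1 (-2.33 ± 0.36) and LDHA (-1.54 ± 0.33) were lower. GZMH was higher (2.78 ± 0.60) and GZMA lower (-2.59 ± 0.74), though with the number series as a term GZMA lost its call (-0.83 ± 0.76). GZMB did not pass (-0.81 ± 0.43). ADGRG1 (4.82 ± 0.56), CX3CR1 (4.03 ± 1.04), TYROBP (3.39 ± 0.60), TBX21 (2.08 ± 0.40), SERPINB9 (1.79 ± 0.33), NKG7 (1.29 ± 0.34) and the TGF-beta co-receptor TGFBR3 (2.72 ± 0.47) were higher. MCL1 (1.34 ± 0.21), CASP8 (1.79 ± 0.36), PSAP (3.56 ± 0.43), ASAH1 (2.22 ± 0.27, adjusted p = 6.4e-08) and the ganglioside synthase ST3GAL5 (1.37 ± 0.24) were higher. Activation of normal CD8-enriched cells itself lowered ADGRG1, CX3CR1, TGFBR3, MCL1, CASP8, PSAP and, though not under every scaling, ASAH1. PLPP1 (-2.25 ± 0.36), BCL2 (-2.22 ± 0.48) and BAX (-2.68 ± 0.58) were lower. S100A8 (8.12 ± 0.53), LYZ (7.09 ± 0.56), CXCL8 (6.18 ± 0.82) and HBB (6.38 ± 1.27) headed the rises. PRF1 (1.27 ± 0.48) and S1PR5 (2.18 ± 0.88) passed, though not under every scaling, and RPL8 behaved likewise. RPL18 had a probe set called in the opposite direction.

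Limma called 3373 genes against activated CD8-enriched cells, 1874 higher and 1499 lower of 8797, a share higher of 55.6% and of 44% under median centring. The cell cycle list fell in 26 of 26 genes (median -3.68, camera adjusted p = 6.2e-35, and 4.7e-05 with an estimated correlation). Lower lists were glycolysis (11 of 15, median -1.17, adjusted p = 7.4e-05), T cell activation (6 lower and 2 higher of 17, median -0.68, adjusted p = 0.00589), naive T cell (7 of 17, median -0.47, adjusted p = 0.0258) and pan T cell (4 of 16, median -0.85, adjusted p = 0.0318), with p of 0.365, 0.274, 0.482 and 0.482 with an estimated correlation. Higher lists were monocyte (18 of 19, median 3.97, adjusted p = 9.9e-12), platelet (8 of 13, 10 adjusted over the list alone, adjusted p = 0.00589), immediate early (9 of 23, median 1.19, adjusted p = 0.00445), B cell (7 of 13, median 1.13, adjusted p = 0.0276), neutrophil (4 of 12, median 1.73, adjusted p = 0.0425) and NK (7 higher and 2 lower of 18, median 1.25, adjusted p = 0.0474). Their p with an estimated correlation were 0.175 for monocyte, 0.493 for neutrophil and 0.482 for the other 4. The sphingolipid list had 10 higher and 3 lower of 29 (11 and 4 adjusted over the list alone, median 0.48, adjusted p = 0.0947), the cytotoxic list 4 and 3 of 14 (median -0.11, adjusted p = 0.966), and the other 9 lists adjusted p of 0.0718 to 0.946.

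Without 1 of the activated CD8-enriched arrays 2236 to 2441 genes were called, the lowest without the third, which moved the count by more than 1.5-fold. Of the 86 named genes, 12, 14 and 10 lost their call without the first, the second or the third. With the number series as a term 1861 genes were called, 1518 of them shared in direction, and 2008 with only the 3 outside patients. The cell cycle list had medians of -4.09 and -4.01 in these fits, the NK list 1.91 and 2.36, the cytotoxic list, which turned from -0.11, 0.41 and 0.57, the monocyte list 4.18 and 5.09, glycolysis -1.25 and -1.29 and the red cell list -0.24 and 0.61. CX3CR1 (5.85 ± 1.18), S1PR5 (4.17 ± 0.91), GZMH (3.75) and PRF1 (2.14) were called with the term. Of the 86 named genes 67 kept their call with it.

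Genes that set patients apart from all 4 normal groups at once numbered 174, with 123 higher and 51 lower of 8584 tested in each. Independent calls would give 3.91 and 0.261, but the comparisons share the patients and the split by number series. Part of the excess may come from either. A set of 20 simulations with no change gave 0, but without change almost no gene is expected to be called, so they set no level. HBB and HBD were the furthest higher, and with the number series as a term neither remained. ZEB2, a repressor that drives terminal effector differentiation, was higher by at least 2.46 in every comparison, and GPR153, an orphan receptor, by at least 1.90. Lower everywhere were HP1BP3 (by at least 2.50), the lymphoid cytokine LTB (2.32), CD27 (2.21), PDAP1 (2.05), GZMK (1.76) and the lipid phosphatase INPP4B (1.69). SERPINB9, TBX21 and STAT3 were also higher, and LEF1, TXK and IL18RAP lower, against all 4 groups. In the fits with the series term the smallest size among the 4 differences was 0.21 for HP1BP3, 0.036 for PDAP1, 0.32 for GZMK and 0.042 for STAT3. It was 1.34 for LTB, 1.23 for CD27 and 1.23 for LEF1, and none of these genes was then called against all 4 groups. With the series term 14 genes set patients apart, 7 in each direction, and 3 were shared, namely ZEB2 (by at least 1.66), FLT3LG and DGKA. The other 11 were GADD45A, PRSS23, PRF1, TTC38, STOM, SLC46A3, PRKCA, TRAF3IP2, SYT11, DHRS3 and MAST4.

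**Figure D3:**
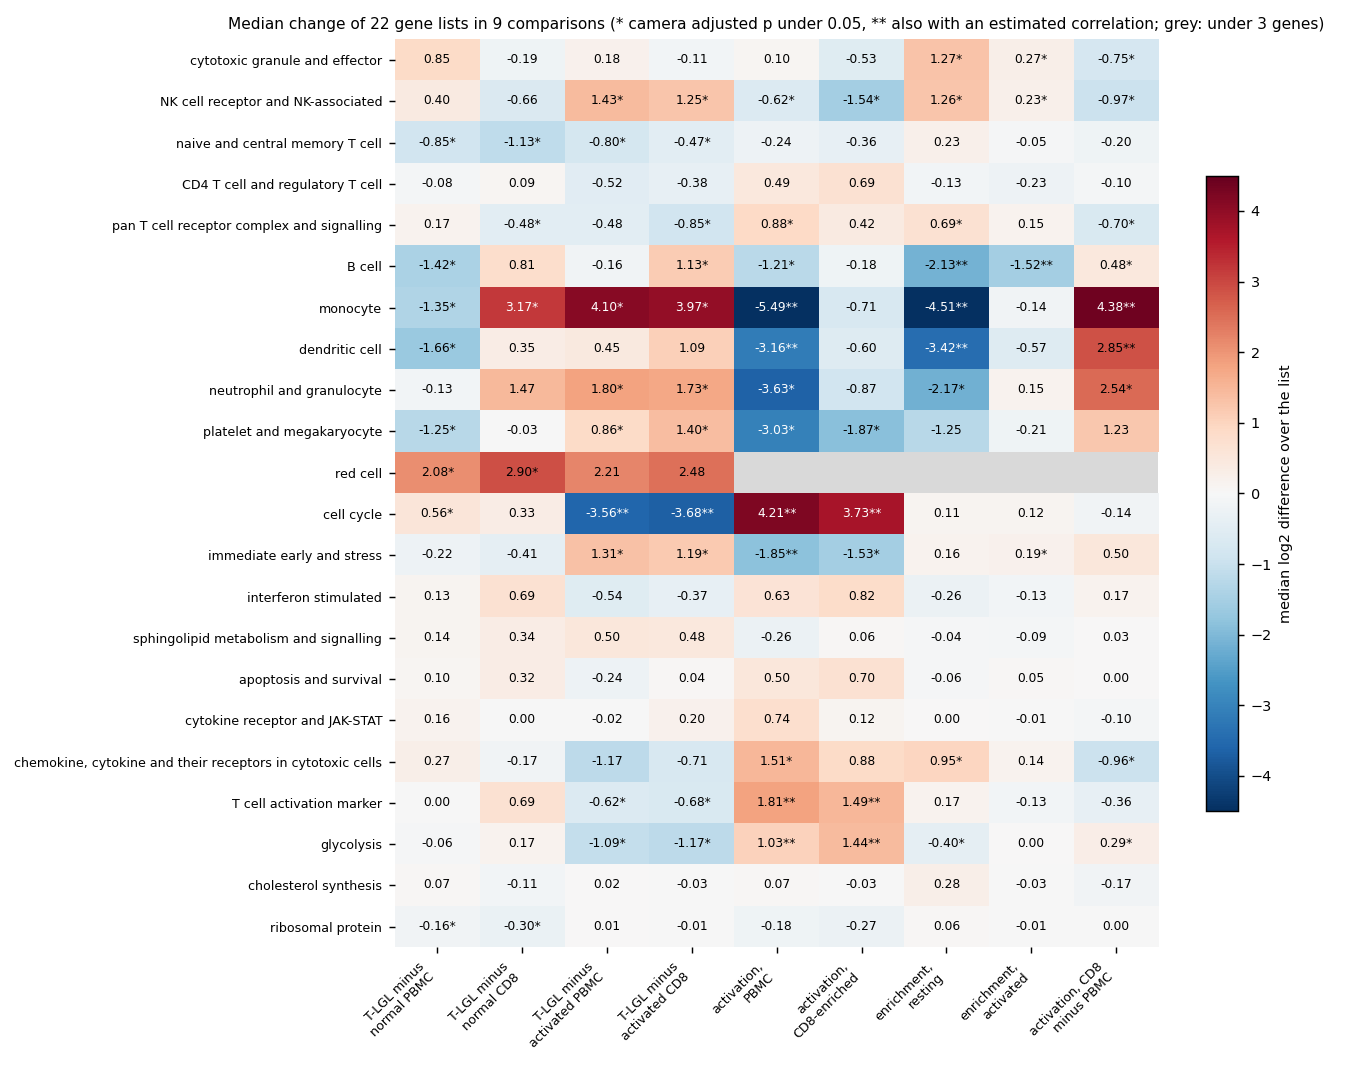
Median log2 difference (colour and number) of 22 gene lists (y axis) in 9 comparisons (x axis), n = 30 and 3 or 3 and 3; an asterisk is a camera adjusted p under 0.05, a pair of them also holds with an estimated correlation, and grey marks lists with under 3 tested genes. The cell cycle list ran from -3.68 in patients against activated CD8-enriched cells to 4.21 on activation in PBMC.

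Activation of normal PBMC, the reference for a normal T cell response, raised genes of cell division (n = 3 and 3 for all comparisons among normal subjects). RRM2 rose by 5.90 ± 0.30 (adjusted p = 3e-07), ASPM by 5.81 ± 0.43, CDC20 (a trigger of mitotic exit) by 5.51 ± 0.53 and TPX2 (a spindle factor) by 4.85 ± 0.24. IL2RA (4.44 ± 0.26), LTA (3.80 ± 0.37), CISH (3.40 ± 0.30), CTLA4 (2.18 ± 0.31) and the T cell factors IRF4 (2.33 ± 0.23) and BATF (2.24 ± 0.27) rose. GZMA (1.89 ± 0.21) and GZMB (1.46 ± 0.34) rose, as did the death receptor FAS (1.33 ± 0.28), its ligand FASLG (1.18 ± 0.29) and BAX (1.53 ± 0.28). GPI (2.47 ± 0.31) and PFKP (2.11 ± 0.25) of glycolysis rose. Of the sphingolipid genes PLPP1 (3.68 ± 0.65) and SGPP1 (0.76 ± 0.21) rose, and PSAP (-3.62 ± 0.32), ASAH1 (-2.35 ± 0.29) and CERS6 (-1.17 ± 0.23) fell.

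Monocyte genes fell over the 10 days of activation, with S100A8 at -8.60 ± 0.65, CD14 at -8.15 ± 0.38, FCN1 at -7.71 ± 0.61 and VCAN at -6.15 ± 0.29. The platelet chemokine PPBP fell too (-7.22 ± 1.15), while the platelet list did not pass with an estimated correlation. The stress response genes FOS (-6.84 ± 0.86), DUSP1 (-5.57 ± 0.40) and NR4A2 (-4.46 ± 0.48) fell. NK receptors KLRF1 (-3.31 ± 0.56), KLRB1 (-2.52 ± 0.34) and KLRG1 (-1.39 ± 0.26), CX3CR1 (-2.82 ± 0.54) and MCL1 (-1.68 ± 0.25) fell. PRF1 (-0.23 ± 0.39), GNLY (0.09 ± 0.39) and CCR7 (0.28) were not called. PAX5, MX2, IL7R (-1.28 ± 0.38) and S1PR1 (-0.79 ± 0.26) were called, though not under every scaling.

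On activation of PBMC limma called 2390 genes, 1375 higher and 1015 lower of 7772, a share higher of 57.5% and of 71.9% under median centring. Camera called the cell cycle list up (26 of 26, median 4.21, adjusted p = 1.7e-23, and 0.00095 with an estimated correlation), T cell activation up (11 higher and 2 lower of 17, 12 and 2 adjusted over the list alone, median 1.81, adjusted p = 0.000587, and 0.039 with an estimated correlation) and glycolysis up (10 of 15, 11 adjusted over the list alone, median 1.03, adjusted p = 0.000132, and 0.0418 with an estimated correlation). It called monocyte down (19 of 19, median -5.49, adjusted p = 3.9e-19, and 0.0281 with an estimated correlation), dendritic down (6 of 6, median -3.16, adjusted p = 0.000132, and 0.0271) and immediate early down (17 of 23, median -1.85, adjusted p = 5.1e-11, and 0.0347). Calls lost with an estimated correlation were pan T cell (median 0.88, adjusted p = 0.195 with it), chemokine (1.51, 0.386), NK (-0.62, 0.386), B cell (-1.21, 0.0666), neutrophil (-3.63, 0.132) and platelet (-3.03, 0.386). The sphingolipid list had 4 genes higher and 6 lower of 24 (median -0.26, adjusted p = 0.198) and the cytotoxic list 3 higher and 1 lower of 14 (median 0.10, adjusted p = 0.592), and the other 7 lists had adjusted p of 0.13 to 0.99. Without any 1 subject 1304 to 1500 genes were called, 16, 17 and 19 of the 89 named genes losing their call in turn with the same genes tested, and with the subject as a block 2733.

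Activation of CD8-enriched cells gave the same replication genes, with RRM2 at 6.09 ± 0.30 (adjusted p = 8e-07), KIF11 (a spindle motor) at 5.74 ± 0.43, CDK1 at 5.43 ± 0.44 and IL2RA at 4.34 ± 0.26. The cytokine LIF (5.42 ± 0.54), the death ligand TNFSF10 (3.98 ± 0.44), CD86 (3.88 ± 0.40), HK2 (3.63 ± 0.47), CISH (3.18 ± 0.30), TPI1 of glycolysis (2.67 ± 0.21), FADD (1.76 ± 0.36) and FAS (1.44 ± 0.28) rose. Also lower were ADGRG1 at -3.65 ± 0.53, CX3CR1 at -2.86 ± 0.54, KLRG1 at -2.45 ± 0.26, KLRF1 at -3.72 ± 0.56 and GZMK at -2.20 ± 0.39. SKIL (-4.52 ± 0.32), NR4A2 (-5.36 ± 0.48), DUSP2 (-4.13 ± 0.27), TGFBR3 (-2.91 ± 0.23), NELL2 (-2.59 ± 0.42), IL7R (-2.22 ± 0.38), CASP8 (-1.81 ± 0.33), CD28 (-1.60 ± 0.33), PSAP (-1.31 ± 0.32) and MCL1 (-1.06 ± 0.25) fell. GZMB (0.54 ± 0.34), PRF1 (-0.57), GNLY (-0.49) and FASLG (-0.19) were not called. GZMA, CD2, VCAN, SC5D, S1PR1 and ASAH1 (-0.89 ± 0.29) were called, though not under every scaling.

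On activation of CD8-enriched cells limma called 2141 genes, 1189 higher and 952 lower. Camera called the cell cycle list up (26 of 26, median 3.73, adjusted p = 4.4e-25, and 0.00075 with an estimated correlation), T cell activation up (10 of 17, 12 adjusted over the list alone, median 1.49, adjusted p = 5.6e-07, and 0.0132) and glycolysis up (12 of 15, 13 adjusted over the list alone, median 1.44, adjusted p = 5.6e-07, and 0.021). The NK list (10 of 16 lower, 11 adjusted over the list alone, median -1.54, adjusted p = 3.8e-06), immediate early (14 lower and 1 higher of 23, median -1.53, adjusted p = 1.7e-06) and platelet lists (5 of 12, median -1.87, adjusted p = 0.00296) fell, with p of 0.157, 0.139 and 0.601 with an estimated correlation. The sphingolipid list had 3 genes higher and 6 lower of 24 (median 0.06, adjusted p = 0.567), the cytotoxic list 3 and 4 of 14 (median -0.53, adjusted p = 0.316), and the other 13 lists adjusted p of 0.0626 to 0.648. Without 1 subject 1278 to 1304 genes were called, 22, 21 and 20 of the 81 named genes losing their call in turn with the same genes tested, and with the subject as a block 2476, where BLNK was not called.

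CD8 enrichment of resting PBMC lowered genes of monocytes, dendritic cells and B cells and raised CD8 genes. CD8A rose by 2.04 ± 0.35, CD8B by 1.88 ± 0.37, GZMK by 1.93 ± 0.39, GZMB by 1.43 ± 0.34, GZMA by 1.19 ± 0.21, NKG7 by 1.45 ± 0.38 and the NK receptor KLRC4 by 1.79 ± 0.37. IFNG (1.96 ± 0.40), FASLG (1.25 ± 0.29), IL21R (1.86 ± 0.43), TGFBR3 (1.55 ± 0.23) and MYO6 (3.41 ± 0.50) rose. CD14 (-7.49 ± 0.38, adjusted p = 4.6e-07), VCAN (-7.25 ± 0.29), LYZ (-6.89 ± 1.82), FCN1 (-6.88 ± 0.61), CD86 (-5.03 ± 0.40), CD4 (-4.40 ± 0.59), CD1C (-3.27 ± 0.36), PAX5 (-3.28 ± 0.35) and MS4A1, the CD20 antigen of B cells (-2.44 ± 0.27), fell. PSAP (-2.39 ± 0.32), GM2A (-3.07 ± 0.58) and ASAH1 (-1.43 ± 0.29) fell too. ANKRD55, MCM4, SPTLC2, BID and IL6R were called, though not under every scaling.

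In limma 580 genes changed on enrichment of resting PBMC, 180 higher and 400 lower, a share higher of 31% and of 41.4% under median centring. Lists called down that held with an estimated correlation were monocyte (19 of 19, median -4.51, camera adjusted p = 1.5e-30, and 0.00647), B cell (9 of 12, 12 adjusted over the list alone, median -2.13, adjusted p = 8.8e-12, and 0.00255) and dendritic (6 of 6, median -3.42, adjusted p = 7.4e-09, and 0.00255). Cytotoxic (5 of 14, 8 adjusted over the list alone, median 1.27, adjusted p = 0.000183), NK (5 higher and 1 lower of 16, 9 and 1 adjusted over the list alone, median 1.26, adjusted p = 3.9e-05), pan T cell (3 of 16, 9 adjusted over the list alone, median 0.69, adjusted p = 1.6e-05) and chemokine (median 0.95, adjusted p = 0.00258) lists rose, with p of 0.202, 0.196, 0.136 and 0.196 with an estimated correlation. Neutrophil (median -2.17, adjusted p = 0.00226) and glycolysis (median -0.40, adjusted p = 0.0186) lists fell, both with p of 0.196 with an estimated correlation, and the other 12 lists had adjusted p of 0.0868 to 0.946. Without 1 subject 164 to 184 genes were called, or 223 to 283 with the same genes tested, 26, 33 and 26 of the 59 named genes then losing their call in turn, and with the subject as a block 780.

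In the comparison of CD8 enrichment after activation MS4A1 was the single gene called (-2.10 ± 0.27, adjusted p = 0.0415), with 136 genes at an unadjusted p under 0.05, and it lost the call without any 1 subject or with the subject as a block, where limma called 0 and 207 had an unadjusted p under 0.05. The B cell genes BLNK (-2.85 ± 0.44), PAX5 (-2.21 ± 0.35) and BANK1 (-2.39 ± 0.49) and the co-receptors CD4 (-2.12 ± 0.59), CD8B (0.91 ± 0.37) and CD8A (0.68 ± 0.35) were not called. The B cell list fell (7 of 12 adjusted over the list alone, median -1.52, camera adjusted p = 1.7e-24, and 0.000211 with an estimated correlation). Cytotoxic (median 0.27, adjusted p = 0.00606), NK (0.23, 0.0264) and immediate early (0.19, 0.0156) lists rose slightly, with p of 0.503, 0.558 and 0.503 with an estimated correlation, and the other 17 lists had adjusted p of at least 0.0835.

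The change on activation was also compared between CD8-enriched and whole PBMC, as the interaction of both factors. FCN1, CD14 and VCAN differed by 7.60 ± 0.86, 7.50 ± 0.54 and 7.08 ± 0.41. On the activated arrays they lay below the array median, so these sizes depend on the pseudocount (6.83, 6.64 and 6.56 with 53.8, and 8.28, 8.25 and 7.41 with 1). They fell on activation of whole PBMC, and enrichment had lowered them in resting cells. CD86 differed by 5.12 ± 0.56 and the antigen presenter CD1C by 2.78 ± 0.51. DUSP2, a phosphatase of activated T cells, went the other way at -1.87 ± 0.38. Limma called 136 genes, 121 in favour of CD8-enriched cells and 15 against, and 3 to 16 without 1 subject, or 28 to 59 with the same genes tested. The monocyte list (12 of 19 genes, 18 adjusted over the list alone, median 4.38, camera adjusted p = 6.0e-33) and the dendritic list (3 of 6, 4 adjusted over the list alone, median 2.85, adjusted p = 1.7e-07) differed, both with p = 0.00758 with an estimated correlation.

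**Figure D4:**
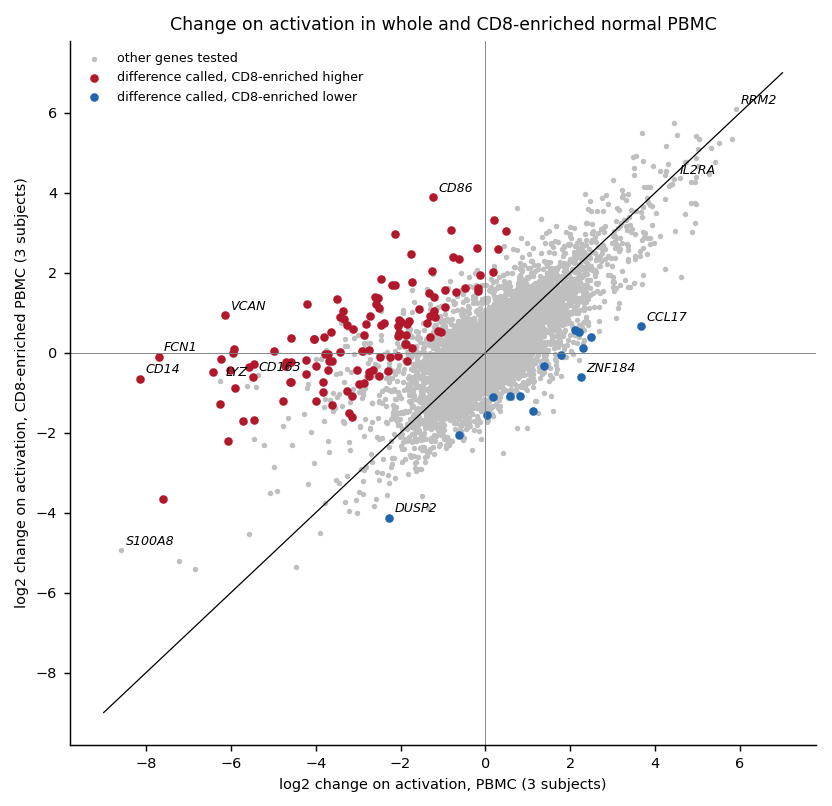
Log2 change on activation in PBMC (x axis) and in CD8-enriched PBMC (y axis), n = 3 subjects each; points are genes, coloured where the difference between both changes was called, and the line marks equal change. The 121 genes with the higher change in CD8-enriched cells include CD14 and VCAN, and RRM2 and IL2RA lie near the line.

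The leukaemia difference was set against the activation change gene by gene, to ask whether patient cells move towards the activated state. Across 8886 genes the difference from normal PBMC correlated with the activation change of PBMC at Pearson r = 0.389, but genes are not independent replicates, and the normal PBMC arrays enter both changes and give a correlation of their own. In 100 simulations with no change these shared arrays alone gave a mean r of 0.662, above the r observed, and a covariance of 0.0936, beside 0.308 observed. With the pooled PBMC sample as the control of the patients no array was shared and r was 0.311. With the number series as a term r was 0.461, but that fit still shares the normal PBMC arrays and was not simulated without change. Of 7504 genes tested in both, 154 were higher in both, 75 lower in both and 23 went opposite ways. Independent lists of these sizes would share 83.5 and 31.2. In 20 simulations with no change at most 3 were shared, but almost no gene is called there, so they set no level for the overlap of changed genes. Part of the excess may come from the shared arrays. The monocyte, dendritic, B cell and platelet lists had negative medians in both changes, so a positive r need not mean a move towards the activated state. The cell cycle list rose on activation, while its median in patients against normal PBMC was 0.56, and 0.03 with the series term.

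Camera's direction differed in sign from a list's median or mean for lists that were not called. These were apoptosis against normal PBMC (median 0.10, test down), cholesterol against CD8-enriched cells, and cytotoxic, apoptosis, cytokine receptor (median 0.20, mean -0.48) and cholesterol against activated CD8-enriched cells. On activation of CD8-enriched cells it was the sphingolipid list (median 0.06, test down). On enrichment they were immediate early (median 0.16, mean -0.28), cytokine receptor and T cell activation (median 0.17, mean -0.32) in resting cells, and apoptosis, ribosomal, cholesterol and glycolysis in activated cells. For the interaction they were the CD4 T cell and T cell activation lists. The median of all genes tested was 0.11 against normal PBMC, 0.12 and 0.13 against CD8-enriched cells and activated PBMC and 0.14 against activated CD8-enriched cells, so ribosomal medians of -0.16 and -0.30 lie further below the typical gene than below 0. Median centring moved it from 0.06 to 0.26 on activation of PBMC, from 0.07 to 0.22 on resting enrichment and from -0.08 to -0.19 for the interaction.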

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

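The counts over other draws of the arrays and the counts with the same genes tested were chosen after the result was seen, and the test of the monocyte and dendritic cell explanation was written before it. Each result here is a difference between groups: the change on activation differed between CD8-enriched and whole PBMC of the same 3 subjects by limma's interaction term or by camera on it.

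The difference was called for 136 genes. Of the genes named by the rule, higher changes in CD8-enriched cells were found for FCN1 (7.60), CD14 (7.50), VCAN (7.08), CSTA (6.07), CPVL (6.01), SERPINA1 (5.94), CD86 (5.12), CD163 (4.88), CD1D (4.48), DEFA4 (3.68), CCR1 (2.96), CD74 (2.81), CD1C (2.78), PSAP (2.31), BCL2A1 (2.18) and TIMP1 (2.11). Lower changes were found for CCL17 (-3.01), ZNF184 (-2.87), CYP2D6 (-2.57), HSPBP1 (-2.19), CCRL2 (-2.10), RSF1 (-1.91) and DUSP2 (-1.87). CCL17, ZNF184, HSPBP1 and CCRL2 did not pass under every scaling, and CCL17 and CD1D did not pass with the subject as a block. Without 1 subject 3 to 16 genes were called. The filter then left 11 of these 23 genes untested at least once, CD14 and VCAN among them. With the same genes tested as before, 28, 39 and 59 genes were called without the first, the second or the third subject, 16, 15 and 15 of the 23 lost their call, and FCN1, CD14 and VCAN kept it each time. Among lists the medians of the difference were 4.38 for monocyte, 2.85 for dendritic cell, 2.54 for neutrophil, 0.48 for B cell, 0.29 for glycolysis, -0.75 for cytotoxic, -0.97 for NK, -0.70 for pan T cell and -0.96 for chemokine genes. Only the monocyte and dendritic lists kept their call with an estimated correlation (adjusted p = 0.00758 each). The other 7 had adjusted p from 0.273 to 0.515 with it.

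A candidate explanation is RNA of monocytes and dendritic cells, which resting whole PBMC contain and CD8 enrichment takes away. If so, genes with a positive difference outside the lists would rise and fall with the monocyte list across the separate set of 30 patients. Their median correlation with it was 0.632 over 106 genes outside the lists, of which 93 were above 0.3 and 1 was below 0. Random draws of as many genes had a median of -0.072, and 0 of 10000 draws were as high. Of the 15 genes with a negative difference 13 were tested in the patients and had a median correlation of -0.264, so the test bears on most of the 106 genes it covered. The 13 of them that did not exceed 0.3 and the negative ones stay open, and a difference in the response of CD8 cells themselves was not tested.

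Of 100 draws of groups of the same sizes, 10 gave at least the 136 genes of the real groups, and the highest of the others gave 398, so by this count chance cannot be excluded. Yet all 9 other draws with as many genes kept the resting arrays in their groups, so they carry the real resting difference and are no measure of chance. The highest with resting arrays mixed was 2. This points to the difference between both resting groups as the structure behind the count.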

How the results depend on the processing

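Fits on the number series, with the 3' to 5' ratio as a term, without the 2 arrays of high ratio, and without 1 array or subject but with the same genes tested were chosen after the data were seen. The other settings were planned. For each result that changed, the cause was not tested, except that fewer genes or arrays enter by construction in the filters, the fits on 3 patients and the fits without an array.

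Against normal PBMC the count of 932 was 495 with a filter at the 75th percentile and 1606 with array weights. It was 308 to 486 without 1 normal array (both ways of filtering, here and in all that follows). It was 837 with the GAPDH ratio as a term and 282 with that ratio and without the 2 arrays of high ratio. With the series term it was 160, and with only the 3 outside patients 254. Fits against the pool have 1 control array, so no counts are given for them. Against CD8-enriched cells the 1524 became 905 with the filter at the 75th percentile, 2327 with probe sets taken singly and 999 at 2-fold or more. The count was 574 to 846 without 1 array, 383 with the series term and 466 with the 3 patients. Against activated PBMC the 3284 became 2094 to 2447, 1764 with the term and 2057. Against activated CD8-enriched cells the 3373 became 2236 to 2542, 1861 with the term and 2008. Without 1 array activation gave 1304 to 1505 genes in PBMC and 1164 to 1304 in CD8-enriched cells, and resting enrichment 164 to 283. Enrichment after activation gave 3 as deposited and 3 with centring, 2 with probe sets singly, 0 with the block (limma) and 0 to 2 without 1 array. The interaction gave 84 without a filter, 225 with probe sets singly and 3 to 59 without 1 subject. Genes apart from all groups numbered 85 at 2-fold or more and 14 with the term. The correlation with activation was 0.311 against the pool and 0.461 with the term, where normal PBMC arrays are still shared.

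Reversals against normal PBMC were HBB (-0.19) and HBD (-0.35) with the term, HBB (-0.56) in the 3 outside patients and, against the pool, HBB (-0.22), HBD (-1.25), IDO1 (-0.0772), IKZF2 (-0.70), MAD2L1 (-0.27), TPX2 (-0.17), ARSA (-0.42), BCL2L1 (-0.89) and IL21R (-0.24). Against CD8-enriched cells the pool reversed VCAN (-0.22), SPIB (-0.31), BLK (-0.0165), CD1D (-0.15), CDK1 (-0.79), CXCL2 (-1.10), CXCL8 (-0.24), NR4A1 (-0.18), BCL2 (0.18), PDGFB (-0.14), HK2 (-1.22) and FDPS (0.23). The term reversed HBB (-0.0583) and FDPS (0.21) there, the 3 patients HBB (-0.87) and FDPS (0.16), and CASP10 was -0.34 as deposited and -0.50 with centring. RPL30 against activated PBMC was -0.13 with centring, HBD with the term was -0.23 and -0.36 against activated PBMC and activated CD8-enriched cells, and VCAN on CD8-enriched activation was -0.0646 with the mean of probe sets. With the term the red cell list against normal PBMC reversed (adjusted p = 0.349), as did the cytotoxic list against CD8-enriched cells (adjusted p = 0.0235, and 0.534 with an estimated correlation).

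Of 540 calls of named genes 520 were kept as deposited, 511 with centring and 496 without a filter, and of 287 in the patient comparisons 174 were kept with the term. Of 73 list calls 17 were kept with an estimated correlation and 56 lost, and with fry 56 were kept, 17 lost and 26 of the 120 others called. GAPDH in place of ACTB for the 3' to 5' ratio gave 2 stronger and 2 weaker differences. Low intensities limit the folds of genes near background, where pseudocounts of 53.8 and 1 each kept 528 of the 540 calls.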

Other observations

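The tests on the number series and on the 3' to 5' ratio and the counts over other splits of the arrays were chosen after the result was seen, and the test of dilution was written before it. The ratio test was first made on all 6 lists together, where it left the question open, and was parted into 4 and 2 lists by its outcome.

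Among the 22 lists, patients differed most among themselves in the means of the red cell, neutrophil, platelet and monocyte lists. Over the 27 patients of 1 number series the SD of the list mean was 1.74 for red cell, 1.49 for neutrophil, 0.976 for platelet, 0.939 for monocyte, 0.797 for interferon and 0.748 for immediate early genes. Random lists of the same sizes had median SDs of 0.220, 0.208, 0.188, 0.132, 0.137 and 0.121, and none of 10000 was as wide. The NK, naive T cell and cytotoxic lists were also wider than all random lists. Genes that vary together widen the mean of their list, so random lists of unrelated genes do not rank the lists. NK (0.584), naive T cell (0.480) and cytotoxic (0.464) lists varied less, and sphingolipid (0.169), cytokine receptor (0.168) and ribosomal (0.146) lists least, the last at the 61st percentile of random lists. Among single genes the chemokine CCL2 (3.44), the granule protein LTF (3.20), the haem enzyme ALAS2 (2.77), osteopontin SPP1 (2.48), CEACAM8 (2.44), the NK receptor KLRC3 (2.26) and IFI44L (2.11) were among those with the largest SDs. These genes were chosen after their values were seen.

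Across the same 27 patients, 21 lists were correlated with the cytotoxic list mean (permutation tests, two-sided, adjusted over 21 relations). The NK list went with it (Pearson r = 0.755, p = 2e-05, adjusted p = 0.00042, Spearman rho = 0.766, adjusted p = 0.00084), and 0.699 without the 2 patients farthest from the median. The naive T cell list went against it (r = -0.612, adjusted p = 0.00704, rho = -0.662, adjusted p = 0.00315), and -0.548 without those 2. The CD4 T cell list did so as well (r = -0.565, adjusted p = 0.0144, rho = -0.570, adjusted p = 0.0143), and -0.459 without them. The cytotoxic and NK lists have no gene in common, and GZMB, which the T cell activation list also holds, was left out of that list here. Over all 30 patients r was 0.806, -0.624 and -0.516, and without the 2 arrays of high 3' to 5' ratio 0.788, -0.583 and -0.558. The pan T cell list had r = 0.437 (adjusted p = 0.0905) and rho = 0.518, which passed (adjusted p = 0.0262). The sphingolipid list had r = -0.362 (adjusted p = 0.124) and the interferon list 0.336 (adjusted p = 0.139), which did not pass.

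Lower naive T, B, monocyte and dendritic lists against normal PBMC may reflect blood filled with expanded cytotoxic lymphocytes. The cytotoxic and NK lists had positive medians but were called only with the series as a term. With the number series as a term the smallest of the 6 medians was still 1.04 in size and all kept their direction. This argues against the series as the whole cause for the cytotoxic, naive T and dendritic medians. The NK, B cell and monocyte lists did not pass with an estimated correlation, so for them the series stays open. The term itself rests on 3 outside patients and 2 pooled arrays. The pooled CD8-enriched array had a higher monocyte list mean than each subject's CD8-enriched array, so its cell content may enter the term. RNA breakdown was tested with each array's log2 GAPDH 3' to 5' ratio as a term, with and without the 2 arrays of high ratio. With that term the NK, naive T, B and monocyte medians kept at least 0.885 of their size. The cytotoxic and dendritic medians kept at least 0.740 but with a wide spread over genes. For the naive T, B and monocyte medians these values argue against a linear effect of that ratio as the whole cause. The NK median, 0.40 without the ratio term, became 1.98 and 2.21 times that size, so it moved with the ratio and no conclusion is drawn for it. Yet the lists were parted by this same outcome, and 1 ratio need not follow all RNA breakdown, so breakdown itself was not excluded. The term left 837 genes called, and 282 without those 2 arrays, where the median size of the 932 differences went from 1.16 to 1.04 and their median SE from 0.30 to 0.34. Dilution by expanded cells predicts that all 4 lower lists fall as the cytotoxic list rises from patient to patient. The naive T cell list did (r = -0.612, adjusted p = 0.00704), and the monocyte (-0.427, adjusted p = 0.0905, and -0.226 over all 30 patients) and dendritic (-0.398, adjusted p = 0.104) lists had negative r that did not pass. By rank the dendritic list passed (rho = -0.562, adjusted p = 0.0143) and the monocyte list did not (-0.465, adjusted p = 0.0506). The B cell list had r = 0.260 (adjusted p = 0.265), so dilution stays open.

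Higher red cell genes in patients may follow the number series and not the disease. If the series were the cause, the red cell list would lose its rise with the series as a term, and its median went from 2.08 to -0.525, with HBB at -0.19. In the fit the series term called 6 of 8 red cell genes higher inside the series (median 2.68), so the values met what the explanation required. What differs between the series, such as the handling of blood or the date of hybridisation, is not in the labels. Within patients the 3 outside and 27 inside the series differed in 1269 of 8566 genes, and the highest of 100 random draws of 3 patients gave 183. Differences inside and outside the series were alike in patients, PBMC and CD8-enriched cells, with r of 0.69, 0.62 and 0.60 across 6603 genes.

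Other splits of the arrays into groups of the same sizes were counted for each comparison. Against normal PBMC 1 of 100 splits, the real one, gave as many genes as the real 932 (highest other 97), so a random division of these arrays seldom gives such a count. The same held against CD8-enriched cells (1 of 100, 1524 and highest other 148), activated PBMC (1 of 100, 3284 and 478) and activated CD8-enriched cells (1 of 100, 3373 and 1452). The splits do not hold the number series apart from the groups, since all normal subjects' arrays and only 3 patients lie outside it. They bear on random division alone and do not part disease from series. With the series as a term the counts were 160, 383, 1764 and 1861. Comparisons among 3 and 3 arrays have 10 splits, too few for a share under 0.05. Real and highest other counts were 2390 and 0 for activation in PBMC, 2141 and 1 for activation in CD8-enriched cells, and 580 and 2 for resting enrichment, each with the real split as the 1 that gave as many. For enrichment after activation they were 1 and 69, with 2 splits giving as many, a structure of the samples that is not the group, and with the subject as a block limma called 0 genes there.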
